A study of Mus musculus with 6 samples.

How the data were processed

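RNA from tibial cartilage of C57BL/6 mice was measured on Agilent 1-colour mouse expression arrays, with 3 control mice and 3 mice carrying loxP-flanked Adam10 alleles together with a Cre recombinase driven by the Col2a1 promoter (called mutants here). Per the labels' protocols, 100 ng of RNA per mouse was amplified and labelled with the dye Cy3. The label field of the same records names Cy5 instead, and the file headers record a scan of 1 channel. Each sample was assigned to its group and replicate number from its title, and the series text states that the replicates are separate mice.

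The scanner output was made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. Per the file headers, the array design refers to the mouse genome build mm9. The deposited spot values are intensity readings on a linear scale: a processed signal from which Feature Extraction had subtracted background, and the raw median brightness of each spot and of its local background. These values had not been normalized between arrays. The authors' deposited value table is a linear ratio of each listed feature to the 75th percentile of its array, as read from the values themselves. The 75th percentile of every column was 1, the column medians lay between 0.094 and 0.104, and each column correlated with that array's processed signal at r = 1.00. The steps by which the authors made that table are not given in the sources used here, and its scale and centring were inferred from this match.

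Each array held 59305 spots that were not controls, which made up 55681 probes. The files pair probes with accession numbers and carry no column of gene names that was used here, so accessions without their version were matched to a RefSeq gene table of the assembly GRCm38.p6. A current symbol was found for 27656 probes, and the other 28025 kept the name in the files. Because that assembly differs from mm9, no coordinates are given. Control spots and spots that Feature Extraction marked as outliers were left out. The processed signal was put on the log2 scale, the 75th percentile of the non-control spots of its array was subtracted, and spots of one probe were averaged. A probe was kept where it was well above background on at least 3 of the 6 arrays, which requires more than 50% of its spots where it had several. This left 35236 probes, of which 8 were dropped because all their spots were outliers on an array. Each gene was represented by the probe with the highest mean signal over all arrays, giving 25494 tested features, of which 15660 had a symbol and 9834 did not. There were 4113 symbols with several passing probes.

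Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested features and a threshold of 0.05. A second count took features at an unadjusted p below 0.05 and at least 2-fold apart. Values are log2 signals relative to the array's 75th percentile, and differences are mutant minus control. SEs and 95% intervals come from the limma fit, which had 4 residual degrees of freedom per gene. The eBayes prior added 2.42, and the intervals and p-values used the total of 6.42. Levels of different probes are not comparable with each other. Where a probe was not well above background on any array of a group, the fold is given as a lower bound: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

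Gene lists, 34 in all, were written from textbook knowledge before the data were examined, as were the tests, the filter, the rule for named genes and most alternatives. They were tested with limma's camera at its preset correlation between genes of 0.01, with adjustment over the lists, and again with a correlation estimated from the data and with fry. Camera took the array weights, or the trend of variance with signal, in the refits that use them; it has no robust setting. A list score is the mean over its genes of the log2 signal minus that gene's mean over all 6 arrays. Scores were compared with a two-sided exact permutation test, which with 3 arrays against 3 cannot give a p below 0.1. Which lists are described at length was chosen after their results were seen. The genes named are Adam10 and Col2a1, then up to 12 per direction. Genes past the adjusted threshold with separated groups came first, ranked by fold change. The remaining places went to the smallest unadjusted p among genes at an unadjusted p below 0.05 and at least 2-fold apart, leaving out names that are not approved-style symbols. Of each list described, the 4 members with the smallest p could be named. Acp5, Acan, Col10a1, Notch1, Notch2, Hbb-y, Hba-a2, Csf3r, Egfl7, Hes1, Nrarp, Lepr, Kitl, Foxc1, Angpt1 and any other genes outside that rule were chosen after their values were seen.

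The alternatives were normexp background correction (offset 50) with percentile or quantile scaling, quantile or median scaling of the processed signal, the deposited value table, other filters on dim probes, a floor, other rules for several probes, eBayes with trend and robust settings, array weights, the replicate number as a block, and each array left out in turn. Normexp was planned on the mean spot signal. The median spot signal was used instead, since the files used here have no column of that mean. After seeing the data, further fits were added: sex as a block, only arrays with Y-linked signal, only the first row of the slide, without control 1 and mutant 2 together, and with a marrow score as a covariate. That score is the mean of the neutrophil, erythroid and B lymphocyte list scores.

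The analysis was tested on simulated arrays of this comparison, with 25494 features and independent noise of the observed size. At the adjusted threshold it recovered 29.9% of features changed by 1 log2 unit, 85.1% of those changed by 2 and 92.4% of those changed by 3, with 7 false calls. A simulated list of 30 genes shifted by -0.6 was called, and 0 of 33 unshifted lists were. The simulated genes were independent, while in the real lists the estimated correlation between genes reached 0.904 (skeletal muscle). The list simulation therefore does not show how often camera's preset would call unshifted lists of correlated genes. The recovered shares likewise rest on independent noise and on 67, 67 and 66 changed features, in the order above. They do not show that features left uncalled on the real arrays lack changes of that size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value.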

Results

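Transcript levels in tibial cartilage were compared between 3 control mice and 3 mutant mice, in which Cre recombinase under the Col2a1 promoter, active in chondrocytes, acts on floxed alleles of Adam10. Adam10 encodes a membrane-bound protease that sheds the outer parts of cell surface proteins and cleaves Notch receptors. The comparison addresses which transcripts differ in cartilage when Adam10 is deleted in that lineage. All 6 arrays lay on 1 slide and were scanned in 1 run, so neither slide nor scan separates the groups. Between 62.4% and 65.4% of spots per array were well above background, and 0 spots were saturated. The 75th percentile of the processed signal ranged from 510.3 to 631.0 intensity units. The slide's first row held the 3 controls and mutant 1, and its second row held mutants 2 and 3. Signal of Xist, a transcript of females, exceeded that of the Y-linked gene Ddx3y on control 1 and mutant 3, and the reverse held on the other 4 arrays, called here arrays with Y-linked signal. Xist was also above background on mutant 1, and Ddx3y on mutant 3.

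Adam10 signal was lower in every mutant than in every control. Its log2 signal was 1.47 ± 0.22 (SD, n = 3) in controls and -0.41 ± 1.12 (SD, n = 3) in mutants, a difference of -1.88 (SE 0.53, 95% interval -3.16 to -0.60), or 3.68-fold lower. The single arrays read 1.61, 1.58 and 1.21 in controls 1 to 3, and 0.15, -1.70 and 0.31 in mutants 1 to 3. In the limma fit the unadjusted p was 0.0108, the p adjusted over the list of Adam10 and Col2a1 alone was 0.0216, and the p adjusted over all features was 0.987. The exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. Without mutant 2 the difference was -1.24. The p adjusted over the list alone was 0.0738 without control 1, 0.0639 without control 2, 0.0584 on arrays with Y-linked signal and 0.121 with the marrow score as a covariate. One probe measured Adam10, and the labels do not say which exon is floxed, so the probe may lie outside the deleted part. Col2a1, the main collagen of cartilage and the source of the Cre promoter, had a log2 signal of 10.03 ± 0.07 (SD, n = 3) in controls and 9.97 ± 0.12 (SD, n = 3) in mutants. Its difference of -0.07 (SE 0.12, 95% interval -0.36 to 0.22) was within the spread between arrays, and it turned to 0.02 with normexp and quantile scaling. As a list, these 2 genes were called lower with a camera adjusted p of 0.0162 and an adjusted p of 0.344 with an estimated correlation. The list's camera adjusted p was 0.0526 without control 1, 0.0644 with normexp and quantile scaling and 0.0910 with the marrow score as a covariate.

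**Figure D1:**
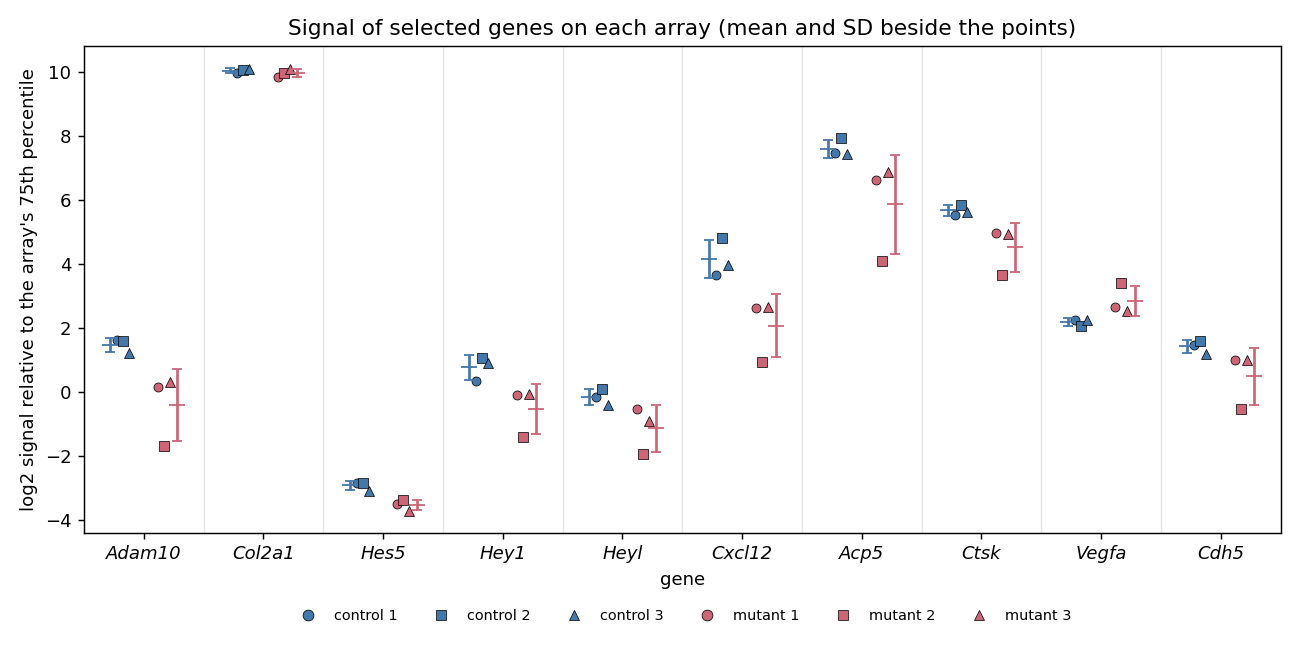
Log2 signal of 10 genes on each array, relative to that array's 75th percentile (y axis), for 3 control arrays (blue) and 3 mutant arrays (red), with marker shapes for replicates 1 to 3 and the mean and SD beside the points. Levels of different genes come from different probes and are not comparable. Adam10 was -1.70 on mutant 2 and 0.15 and 0.31 on the other mutants, and Col2a1 lay near 10 on every array.

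Across all 25494 tested features, limma called 0 higher and 0 lower in mutants at an adjusted p below 0.05, and the smallest adjusted p was 0.388. At an unadjusted p below 0.05 there were 877 features (396 higher and 481 lower), against 1275 expected by chance. The groups did not overlap for 2281 features, or 8.95%, where chance gives 10%. With array weights, limma called 1 feature higher and 3 lower. Of features at an unadjusted p below 0.05 and at least 2-fold apart, 28 were higher and 159 lower, and 11 and 127 of these had a symbol. The lower count was 59 without mutant 2, 66 without control 2, 292 without control 3 and 357 without mutant 3. The higher count was 62 without control 1 and 63 without control 3. With normexp background correction the counts were 0 higher and 68 lower with percentile scaling, and 0 higher and 53 lower with quantile scaling. Without control 1 and mutant 2, the arrays at the ends of the first principal component, they turned to 282 higher and 88 lower. That component held 44.6% of the variance, with control 1 at -55.3 and mutant 2 at 71.0 and the other 4 arrays between -14.0 and 15.2. Correlations between arrays ran from 0.978 to 0.993 within groups and from 0.969 to 0.991 between groups.

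Of the genes at least 2-fold lower, the 12 with the smallest p are named here, and none passed the threshold adjusted over all features. Gpr182, a receptor of sinusoidal and lymphatic endothelium, had a difference of -1.51 (SE 0.20, adjusted p 0.830). Plac8, abundant in myeloid cells, differed by -2.04 (SE 0.40), and Il21r, the receptor for interleukin 21, was at least 1.65-fold lower, with 0 of 3 mutant arrays well above background. Spic, a transcription factor of red pulp and marrow macrophages, differed by -1.82 (SE 0.36). Marco, a macrophage scavenger receptor, differed by -1.06 (SE 0.22). Il1b, the cytokine interleukin 1 beta, differed by -1.18 (SE 0.21). The other named genes were Nxpe2 at -2.06, Tmem178 at -1.81, Dennd2d at -1.36, Cfap161 at -1.11 and Pde9a, a cyclic GMP phosphodiesterase, at -1.01. Ftdc1 was at least 1.51-fold lower, again with 0 of 3 mutant arrays well above background. For each of these 12 genes all 3 mutant arrays lay below all 3 control arrays. The genes were picked for a small p, which favours such separation. With normexp and percentile scaling the differences of these 12 genes kept their sign but ran from -0.22 to -1.70, and 10 of them were smaller by over 1.5 times, Spic among them at -0.98.

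In the higher direction 9 genes with approved-style symbols met the same rule. Irx1, a homeobox transcription factor, differed by 1.39 (SE 0.41), from a log2 signal of -2.62 ± 0.87 (SD, n = 3) in controls to -1.24 ± 0.11 (SD, n = 3) in mutants. Tff2, a secreted trefoil peptide, differed by 1.33 (SE 0.39). Irx1 and Tff2 were well above background on all 6 arrays. The other 7 genes were above background on only 1 or 2 control arrays. These were Syt10 at 1.39, Cd70 at 1.35, Plppr1 at 1.33, Lgsn at 1.33, Zmynd12 at 1.06, Dcpp1 at 1.05 and Mdga2 at 1.02. The adjusted p of each of these 9 genes was 0.987. With normexp and percentile scaling they ran from 0.09 to 0.97, with Irx1 at 0.97, and 8 of the 9 were smaller by over 1.5 times.

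Of the 34 gene lists, camera with its preset correlation called 21 lower and 4 higher in mutants and did not call 9. With a correlation estimated from the data 0 lists were called (smallest adjusted p 0.344, with 1 list at an unadjusted p below 0.05), and fry also called 0 (smallest adjusted p 0.484, with 1 list at an unadjusted p below 0.05). Leaving out control 1 gave 12 lists lower, leaving out mutant 2 gave 12 lower and 2 higher, and array weights gave 13 lower. Scores of the control and mutant arrays did not overlap for 5 lists, or 14.7%, where chance gives 10%. Those lists were the target and driver genes, osteoclasts, macrophages and matrix-degrading enzymes, which were lower, and hypoxia and glycolysis, which was higher (exact permutation p 0.1 each, the smallest possible). In every list except the 3 named here, 0 members passed the threshold adjusted over the list alone. Adam10 passed in its own list, Spic and Marco in the macrophage list, and Il1b in the chemokine list. Of the 57 members with the smallest p in the lists described at length, 33 moved by over 1.5 times when 1 array was left out, 27 of them without mutant 2, and 0 changed sign.

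Of 30 genes of osteoclasts and chondroclasts, the cells that resorb bone and calcified cartilage, 27 had a difference below 0 and 7 of them an unadjusted p below 0.05, with a median of -0.65. As a list they were called lower (camera adjusted p 1.05e-14; adjusted p 0.344 with an estimated correlation), and 0 members passed the threshold adjusted over the list alone. Ctsk, the collagen-degrading cathepsin of osteoclasts, differed by -1.16 (SE 0.37), or 2.23-fold lower, and Rab38 by -1.81 (SE 0.54). Oscar, a receptor that costimulates osteoclast formation, differed by -0.57 (SE 0.17), and the brain-type creatine kinase Ckb by -0.84 (SE 0.28). The brightest member, Acp5 (tartrate-resistant acid phosphatase), read 7.60 ± 0.28 (SD, n = 3) in controls and 5.86 ± 1.54 (SD, n = 3) in mutants. The list score was lowest on mutant 2, at -1.17, against -0.08 and 0.04 on mutants 1 and 3 and 0.21 to 0.55 on controls, and without mutant 2 the median was -0.39. On arrays with Y-linked signal it was -0.98.

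Genes of monocytes and macrophages were below 0 in 29 of 30 cases, with a median of -1.05. Besides Spic and Marco, each with a p of 0.0364 adjusted over the list alone, Lyz2 (lysozyme) differed by -1.42 (SE 0.37) and the lectin Cd209f by -1.49 (SE 0.48). Camera called the list lower (adjusted p 5.72e-17; adjusted p 0.344 with an estimated correlation). Mutant 2 had the lowest score, at -1.66, and without it the median was -0.38. The median was -0.36 on the first row of the slide and -0.62 with array weights. When single arrays were left out, Spic passed the list's own threshold in 1 of 6 fits and Marco in 2 of 6. For Spic the p adjusted over the list alone was 0.151 without control 1, 0.161 without control 2, 0.0765 without control 3, 0.0897 without mutant 1 and 0.0588 without mutant 2. For Marco it was 0.161 without control 1, 0.161 without control 2, 0.0897 without mutant 1 and 0.0588 without mutant 2. Neither gene passed with the replicate number as a block (0.148 for both) or without a filter on dim probes (0.0506 for both). Both also failed to pass on arrays with Y-linked signal (Spic 0.0661, Marco 0.187), on the first row of the slide (0.181 and 0.263), without both control 1 and mutant 2 (0.0869 each) and with the marrow score as a covariate (0.230 each).

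Lists for cells of the marrow and blood followed single control arrays. Neutrophil genes were below 0 in 33 of 35 cases with a median of -1.40, led by Mmp8 (neutrophil collagenase) at -2.70 (SE 0.67) and Clec4d at -1.14 (SE 0.34). Erythroid genes were below 0 in 31 of 33 cases with a median of -0.72, with the erythropoietin receptor Epor at -1.27 (SE 0.43) and the beta globin Hbb-b2 at -1.31 (SE 0.47). The embryonic globin Hbb-y went the other way, at 2.13 (SE 1.09), and was above background on 1 control and 2 mutant arrays. B lymphocyte genes were below 0 in 21 of 26 cases with a median of -1.02, with Blnk, an adaptor of the B cell receptor, at -1.47 (SE 0.55). The interleukin 7 receptor Il7r was at least 2.20-fold lower, with 0 mutant arrays well above background. The lists were called lower with camera adjusted p-values of 1.08e-17, 6.78e-09 and 5.5e-07. With an estimated correlation the adjusted p-values were 0.344, 0.36 and 0.344. The neutrophil score was 1.57 and 0.98 on controls 1 and 2 but -0.66 on control 3, within the mutants' range of -1.02 to -0.18, and the erythroid and B cell scores had the same order of controls. Without control 1 the medians were -0.74 for neutrophils, -0.22 for erythroid cells (camera adjusted p 0.0623, no longer called) and -0.60 for B cells. Without control 3 they were -2.17 for neutrophils and -1.60 for erythroid cells, and without mutant 2 the B cell median was -0.45. The B cell median was -0.57 with normexp and percentile scaling. With control 1 and mutant 2 both left out, the erythroid and B cell calls were lost (camera adjusted p 0.833 and 0.417) and the neutrophil median was -0.81. The marrow score is built from these 3 lists, so it was not used to judge them.

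**Figure D2:**
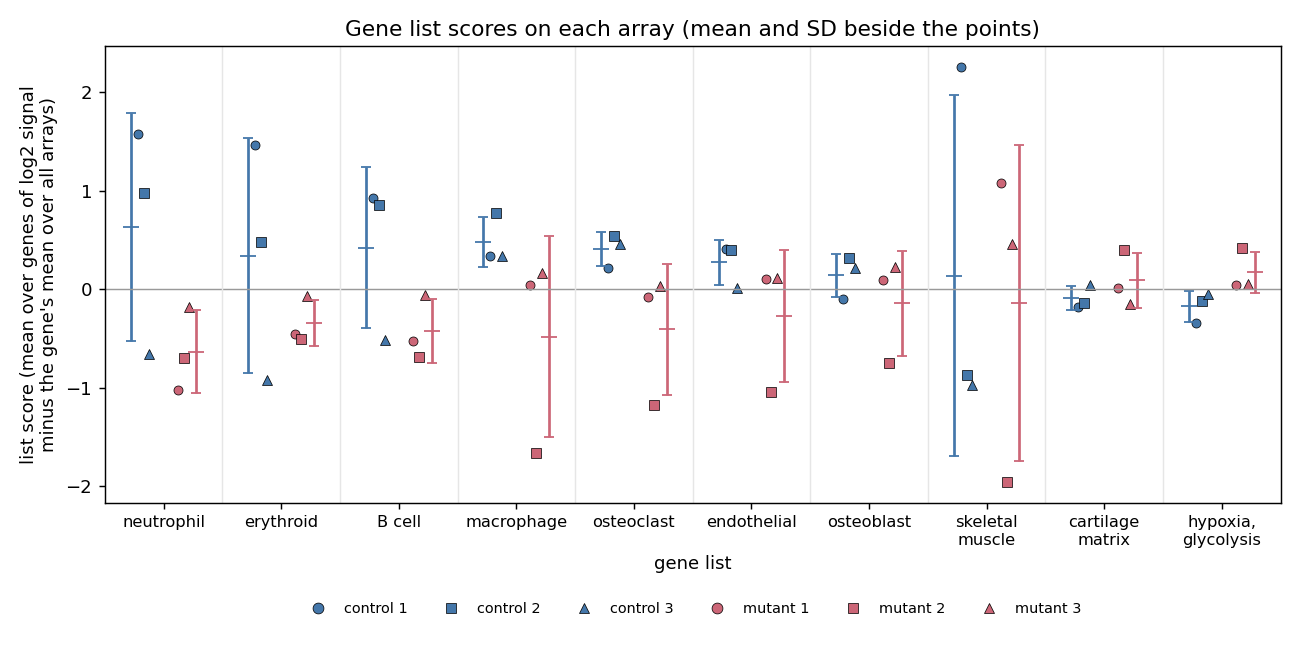
Scores of 10 gene lists on each array (y axis, mean over the list's genes of the log2 signal minus that gene's mean over all 6 arrays), for 3 control arrays (blue) and 3 mutant arrays (red), with marker shapes for replicates 1 to 3 and the mean and SD beside the points. Mutant 2 was the lowest array for macrophages (-1.66), osteoclasts (-1.17) and endothelial cells (-1.05), and control 1 the highest for neutrophils (1.57) and skeletal muscle (2.26).

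Endothelial genes were below 0 in 36 of 39 cases, with a median of -0.59. Stab2, a scavenger receptor of sinusoidal vessels, differed by -1.22 (SE 0.32), Emcn (endomucin) by -0.86 (SE 0.37), Angpt2 by -1.05 (SE 0.46) and Cdh5 (VE-cadherin) by -0.94 (SE 0.43). Without mutant 2 Emcn stood at -0.44, Angpt2 at -0.51 and Cdh5 at -0.43. Tested as a set, the list was lower (camera adjusted p 1.35e-14; adjusted p 0.344 with an estimated correlation). The score was -1.05 on mutant 2 and 0.11 and 0.12 on the other mutants, against 0.01 to 0.41 on controls. Without mutant 2 the median was -0.19. The call was lost with control 1 and mutant 2 both left out (median -0.10, camera adjusted p 0.316), and the median was -0.28 with the marrow score as a covariate, -0.31 with array weights and -0.18 on the first row of the slide.

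In the list of Notch pathway and target genes 21 of 30 members were below 0, with a median of -0.15, and 3 members, all transcription factors induced by Notch signalling, had an unadjusted p below 0.05. Hes5 differed by -0.61 (SE 0.14), Hey1 by -1.30 (SE 0.41) and Heyl by -0.99 (SE 0.37). The receptors Notch1 and Notch2 had differences of -0.08 (SE 0.25) and 0.00 (SE 0.11), chosen for mention after their values were seen. As a set these genes were called lower (camera adjusted p 0.00033; adjusted p 0.344 with an estimated correlation). The call was lost without control 1 (camera adjusted p 0.0526) and without mutant 2 (median -0.03, camera adjusted p 0.0885), and the median was -0.24 without mutant 3 and -0.23 without control 3. It was also lost with array weights (median -0.07, camera adjusted p 0.256), on the first row of the slide (median -0.02, 0.0988), with the marrow score as a covariate (median -0.03, 0.185) and without both control 1 and mutant 2 (median 0.02, 0.833). Mutant 2, with the lowest endothelial score, also had the lowest Notch list score, at -0.49, and with the endothelial score as a covariate the difference of the Notch list score went from -0.27 (SE 0.18) to -0.023 (SE 0.048).

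Genes of the cartilage matrix and of resting or proliferating chondrocytes were above 0 in 34 of 42 cases, with a median of 0.25. Sfrp5, a secreted Wnt inhibitor, differed by 0.73 (SE 0.29), Col11a1 by 0.33 (SE 0.16), Col27a1 by 0.34 (SE 0.18) and the matrilin Matn3 by 0.36 (SE 0.19). Acan, the core protein of aggrecan, differed by 0.36 (SE 0.20). The list was called higher (camera adjusted p 0.000514; adjusted p 0.525 with an estimated correlation). The score was highest on mutant 2, at 0.40, and without that array the median was 0.09 and the call was lost (camera adjusted p 0.446). Without control 1 the median was 0.14. The call was also lost with the marrow score as a covariate (median 0.06, camera adjusted p 0.397), on the first row of the slide (median 0.09, 0.0978) and without both control 1 and mutant 2 (median -0.01, 0.884). On mutant 2 the scores for macrophages, osteoclasts, osteoblasts and endothelial cells were the lowest of the 6 arrays.

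Hypertrophic chondrocyte genes were above 0 in 22 of 28 cases with a median of 0.17 and were not called (camera adjusted p 0.143; adjusted p 0.624 with an estimated correlation). Col10a1, the collagen of hypertrophic cartilage, differed by 0.25 (SE 0.21). Without control 2 the list was called higher (median 0.22, camera adjusted p 0.00308), and without control 1 the median was -0.03. It was also called higher with normexp and percentile scaling (camera adjusted p 0.0207) and with the replicate number as a block (0.0366), and the median was -0.04 with array weights. Hedgehog and PTHrP signalling genes, which set the pace of chondrocyte differentiation, were above 0 in 18 of 21 cases with a median of 0.17. Ptch1, a Hedgehog receptor and target, differed by 0.50 (SE 0.18), Gli3 by 0.23 (SE 0.13) and Pth1r, the PTHrP receptor, by 0.28 (SE 0.19). The list was called higher (camera adjusted p 0.0292; adjusted p 0.344 with an estimated correlation). Its call was lost without control 2 (camera adjusted p 0.188), control 3 (median 0.10, 0.144), mutant 1 (0.235) or mutant 2 (median 0.10, 0.0990). It was also lost with the mean of a gene's probes (median 0.14, 0.0883) and with every probe tested (median 0.12, 0.190).

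Hypoxia and glycolysis genes were above 0 in 33 of 36 cases, 11 of them with an unadjusted p below 0.05, and the median was 0.38. Vegfa, the vascular growth factor, differed by 0.67 (SE 0.24), or 1.59-fold higher. The oxygen-sensing hydroxylases Egln1 and Egln3 differed by 0.48 (SE 0.16) and 0.58 (SE 0.20), and Ndufa4l2, a hypoxia-induced mitochondrial protein, by 0.61 (SE 0.22). Camera called this list higher (adjusted p 9.92e-12; adjusted p 0.344 with an estimated correlation). The score was 0.41 on mutant 2 and 0.04 and 0.06 on mutants 1 and 3, against -0.35, -0.12 and -0.04 on controls. The median was 0.23 without control 1, 0.24 without mutant 2, 0.14 without both, 0.20 with the marrow score as a covariate and 0.19 with array weights.

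Osteoblast and osteocyte genes were below 0 in 23 of 34 cases, with a median of -0.10. The osteocyte genes Phex and Dmp1 differed by -1.24 (SE 0.33) and -1.65 (SE 0.68), and Tnfsf11, the osteoclast differentiation factor RANKL, by -1.17 (SE 0.66). Without mutant 2 Dmp1 stood at -0.84 and Tnfsf11 at -0.36. Camera called this list lower (adjusted p 0.00235; adjusted p 0.466 with an estimated correlation). Mutant 2 had the lowest score, at -0.75, and without it the call was lost (median -0.04, camera adjusted p 0.874). The median was -0.17 without control 3 and -0.20 without mutant 1 or mutant 3. The call was also lost with array weights (camera adjusted p 0.0972), on the first row of the slide (median 0.01, 0.636) and without both control 1 and mutant 2 (0.292).

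Chemokine, cytokine and receptor genes were below 0 in 26 of 36 cases, with a median of -0.38. Il1b had a p of 0.0403 adjusted over the list alone, and it passed in 1 of 6 fits with an array left out. That p was 0.120 without control 1, 0.201 without control 2, 0.0553 without control 3, 0.131 without mutant 1 and 0.0669 without mutant 2. With normexp the difference of Il1b shrank to -0.42 with percentile scaling (p adjusted over the list alone 0.0878) and -0.37 with quantile scaling (0.0513). That p was also 0.0846 with trend and robust eBayes, 0.0588 without a filter on dim probes, 0.120 with the replicate number as a block and 0.159 with the marrow score as a covariate. It was 0.0703 on arrays with Y-linked signal, 0.167 on the first row of the slide and 0.0702 without both control 1 and mutant 2. Cxcl12, a chemokine that retains blood-forming cells in marrow, differed by -2.08 (SE 0.53), or 4.24-fold lower. Its log2 signal was 4.14 ± 0.59 (SD, n = 3) in controls and 2.06 ± 0.99 (SD, n = 3) in mutants. The eosinophil chemokine receptor Ccr3 differed by -0.87 (SE 0.20) and Cxcl10 by -1.69 (SE 0.46). The list as a whole was called lower (camera adjusted p 5.39e-07; adjusted p 0.344 with an estimated correlation), with the lowest score on mutant 2, at -0.81, and a median of -0.10 without that array. The call was lost with the marrow score as a covariate (median -0.21, camera adjusted p 0.0568) and without both control 1 and mutant 2 (0.292), and the median was -0.24 with normexp and percentile scaling.

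The list of other sheddases and their regulators was below 0 in 13 of 22 cases, with a median of -0.13. Adam17, the protease closest to Adam10 in function, differed by -0.24 (SE 0.14), Adam8 by -0.69 (SE 0.41) and the inhibitor Timp3 by 0.25 (SE 0.18). Adam8 stood at -0.28 without mutant 2, and Timp3 at 0.07 without control 1 and 0.38 without control 3. These genes were called lower together (camera adjusted p 0.0108; adjusted p 0.344 with an estimated correlation), and the call was lost without control 1 (camera adjusted p 0.145) or mutant 2 (median -0.03, camera adjusted p 0.464). It was also lost with array weights (median -0.04, camera adjusted p 0.578), on arrays with Y-linked signal (0.0675), on the first row of the slide (0.572) and with the marrow score as a covariate (0.585). Genes for reported ADAM10 substrates were below 0 in 21 of 34 cases with a median of -0.06 and were not called (camera adjusted p 0.0786; adjusted p 0.344 with an estimated correlation), though without mutant 1 they were called lower (median -0.04, camera adjusted p 0.0251). They were also called lower with every probe tested (median -0.12, camera adjusted p 0.00809), with median centring (0.0472) and with the replicate number as a block (0.0411). Efna5, an ephrin, differed by 0.47 (SE 0.12), Egf by 0.30 (SE 0.11), the IgE receptor Fcer2a by 0.49 (SE 0.17) and Sema4d by -0.93 (SE 0.37).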

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

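The fits by sex, slide row, marrow score and without control 1 and mutant 2 were chosen after the data were seen. Adam10 was lower under all 25 refits, by -2.24 to -1.16 on the log2 scale, and its unadjusted p stayed below 0.05 except with the marrow score as a covariate (-1.56, p 0.0607); with single arrays left out it ran from -2.24 to -1.24. At the adjusted threshold every refit gave 0 features higher and 0 lower, apart from array weights with 1 and 3. Features at an unadjusted p below 0.05 and at least 2-fold higher and lower numbered 0 and 68 with normexp and percentile scaling, 0 and 53 with normexp and quantile scaling, 181 and 310 without a filter on dim probes, 203 and 337 with array weights, 68 and 290 on arrays with Y-linked signal, 282 and 88 without control 1 and mutant 2, and 93 and 85 with the marrow score. The higher count was 13 with a filter on all 6 arrays, 14 with a floor, 53 with every probe tested and 47 on the first row of the slide. Leaving out single arrays gave 27 to 63 higher and 59 to 357 lower. Dropping the filter adds tested features (36975 in place of 25494). Normexp adds an offset of 50, against median processed signals of 51.1 to 61.3 per array, and so shrinks log2 differences of dim probes. How far this accounts for the normexp counts, and the cause of the other moves, were not tested. Lists called lower and higher numbered 12 to 22 and 2 to 5 with single arrays left out, 6 and 7 without control 1 and mutant 2, 6 and 5 with the marrow score, 13 and 6 with array weights, and 13 and 4 on the first row. With an estimated correlation they numbered 0 and 0, and with fry 0 and 0. The osteoclast, macrophage, hypoxia, mast cell and cell cycle lists stayed past camera's preset threshold in the same direction under all 25 refits, though not with an estimated correlation or fry. For single lists and all refits, 715 results stayed on their side of the threshold, 65 lost a call, 13 gained one and 56 reversed. The median change of all features stayed within 0.1 of 0 under every scaling. Of the 9 named higher genes 7 were near background in controls.

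Reversed lists are given by their median change, where the direction is that of camera's test; the cause was not tested. Skeletal muscle turned higher without control 1 (0.77) and without mutant 2 (0.68), on arrays with Y-linked signal (0.53), on the first row (0.98), without both arrays (1.74) and with the marrow score (0.90). Under the same last 4 settings tendon gave 0.14, 0.0023, 0.30 and 0.14, and 0.12 without control 1. Adipocytes gave 0.26 without mutant 2, 0.12 on the first row, 0.54 without both arrays and 0.12 with the marrow score. Without both arrays smooth muscle and stroma gave 0.20, sheddases 0.0065, cartilage -0.0054, hypertrophic chondrocytes -0.062, glycosaminoglycan synthesis 0.0022, immediate early genes 0.062, BMP and TGF-beta -0.026 and sex-linked genes -2.39. With array weights muscle gave 1.5003, tendon 0.17, adipocytes 0.26, smooth muscle and stroma 0.029, hypertrophic chondrocytes -0.037, BMP and TGF-beta 0.0084 and immediate early genes 0.050. With the marrow score smooth muscle and stroma gave 0.017, erythroid cells 0.18, hypertrophic chondrocytes -0.0041, immediate early genes 0.24, BMP and TGF-beta 0.028 and sex-linked genes -2.29. On arrays with Y-linked signal hypertrophic chondrocytes gave 0.021, immediate early genes 0.30 and BMP and TGF-beta 0.059. On the first row skin gave 0.079 and BMP and TGF-beta 0.045. BMP and TGF-beta also gave 0.053 with normexp and percentile scaling and 0.034 without a filter. Sex-linked genes gave 0.11 with normexp and percentile scaling and 0.50 with median centring. With single arrays left out the medians ran from -0.033 to 0.23 for hypertrophic chondrocytes, -0.97 to 0.77 for muscle, -0.49 to 0.12 for tendon, -0.70 to 0.26 for adipocytes, 0.055 to 0.095 for Wnt, -0.032 to 0.065 for BMP and TGF-beta, -0.13 to 0.21 for immediate early genes and -1.57 to 1.51 for sex-linked genes. Single genes that reversed were Col2a1 at 0.019 with normexp and quantile scaling, and Bace2 at 0.066 with array weights and 0.035 on the first row.

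With the replicate number as a block (replicate block), 0 features were called higher and 0 lower, 28 and 121 met the 2-fold criterion, 5 lists were higher and 22 lower, the BMP and TGF-beta list reversed at a median of 0.034, and the hypertrophic chondrocyte and ADAM10 substrate lists gained a call. Deviations of same-numbered arrays correlated at 0.207, 0.061 and -0.164. Controls 1 and 2 correlated best with the mutant of their own number, while control 3 correlated best with mutant 2 (0.245), the highest value of all. Whether the numbers pair the samples cannot be told from these values. A slide or scan block could not be fitted, since there was 1 slide and 1 scan.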

Other observations

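Of the tests that weigh explanations, those on scores or Cxcl12 without mutant 2, those on the Notch list score, and the comparisons of osteoclast with osteoblast genes and of Cxcl12 with other stromal markers were chosen only after the result was seen, as were the 3 patterns and the fits by sex, slide row, marrow score and without both control 1 and mutant 2. The marrow test of the osteoclast score was added after other results had been seen but before its own, while the splits and the refits of lists with 1 array left out were planned. Several gene lists outside the main account also differed. Genes of mast cells, eosinophils and basophils were below 0 in 15 of 15 cases, with a median of -0.98. The eosinophil ribonucleases Ear1 and Ear2 differed by -2.18 (SE 0.85) and -2.15 (SE 0.75). Camera called the list lower (adjusted p 2.32e-10; adjusted p 0.344 with an estimated correlation), and the median was -0.61 without control 1 and -0.63 without mutant 2. It was -0.60 with normexp and percentile scaling, -0.29 with the marrow score as a covariate and -0.30 without both control 1 and mutant 2. Interferon-stimulated genes were below 0 in 29 of 35 cases with a median of -0.43. Irf7, an interferon regulatory factor, differed by -0.97 (SE 0.30), the viral RNA sensor Ifih1 by -0.60 (SE 0.23) and the immunoproteasome subunit Psmb8 by -1.40 (SE 0.55). That list was called lower (camera adjusted p 3.04e-09; adjusted p 0.344 with an estimated correlation), with a median of -0.12 without mutant 2 and -0.27 with normexp and percentile scaling. The call was lost with the marrow score as a covariate (camera adjusted p 0.0910) and without both control 1 and mutant 2 (0.990). Matrix-degrading enzymes were below 0 in 28 of 36 cases with a median of -0.25 and were called lower (camera adjusted p 1.22e-05; adjusted p 0.344 with an estimated correlation). Mmp3 (stromelysin) differed by -0.62 (SE 0.29) and the cathepsin Ctss by -1.40 (SE 0.65), and the list shares Mmp8 with the neutrophil list and Ctsk with the osteoclast list. Without control 1 the median was -0.14, and without mutant 2 it was -0.04 and the call was lost (camera adjusted p 0.124). It was also lost with array weights (0.234), on the first row of the slide (0.464), with the marrow score as a covariate (0.185) and without both arrays (0.727). Megakaryocyte and platelet genes were below 0 in 16 of 22 cases, with the platelet integrin Itgb3 at -0.94 (SE 0.38), and were called lower (median -0.26, camera adjusted p 9.17e-05; adjusted p 0.344 with an estimated correlation), with a median of -0.17 without control 1. The megakaryocyte call was lost with the marrow score as a covariate (camera adjusted p 0.585) and without both arrays (0.805). T and NK cell genes were below 0 in 13 of 19 cases, with granzyme A (Gzma) at -1.64 (SE 0.57), and were called lower too (median -0.19, camera adjusted p 0.00298; adjusted p 0.374 with an estimated correlation). Their median was -0.33 without mutant 1 and -0.44 without mutant 3, and the call was lost without control 1 (camera adjusted p 0.0522) and without mutant 2 (median -0.08, camera adjusted p 0.269). It was lost as well with the marrow score as a covariate (0.315) and without both arrays (0.736), and the median was -0.10 with normexp and percentile scaling.

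Cell cycle genes were below 0 in 37 of 45 cases by small amounts (median -0.13, camera adjusted p 5.16e-07; adjusted p 0.454 with an estimated correlation), with Ccnb2 (cyclin B2) at -0.27 (SE 0.12). The median was -0.23 without control 1 and -0.05 without control 2. Genes of the unfolded protein response were above 0 in 24 of 30 cases (median 0.12, camera adjusted p 0.00594; adjusted p 0.525 with an estimated correlation), with the stress pseudokinase Trib3 at 0.70 (SE 0.19). That call was lost without control 1 (median 0.05, camera adjusted p 0.203) and without mutant 2 (median 0.05, camera adjusted p 0.120). It was also lost with array weights (camera adjusted p 0.256), on arrays with Y-linked signal (0.0643), with the marrow score as a covariate (0.381) and without both control 1 and mutant 2 (0.955). Lists for the soft tissue around cartilage moved with single arrays. Members below 0 numbered 42 of 46 for skeletal muscle, 36 of 41 for tendon, ligament and synovium, 17 of 21 for adipocytes and 15 of 25 for smooth muscle, pericytes and marrow stroma. Among them Pparg, the regulator of fat cell formation, differed by -0.44 (SE 0.25) and the growth factor receptor Pdgfrb by -0.43 (SE 0.21). For skeletal muscle (median -0.32, camera adjusted p 0.0333; adjusted p 0.764 with an estimated correlation) the score was 2.26 on control 1, -0.87 and -0.97 on controls 2 and 3, and 1.08, -1.96 and 0.46 on mutants 1 to 3. Leaving out controls 1, 2 and 3 and then mutants 1, 2 and 3 gave muscle medians of 0.77, -0.83, -0.89, -0.97, 0.68 and -0.58. With array weights the muscle, tendon and adipocyte medians turned to 1.5003, 0.17 and 0.26. The muscle call was lost with quantile scaling (camera adjusted p 0.0802), with normexp and quantile scaling (0.0644), with the deposited value table (0.0553) and without a filter on dim probes (0.139). In the same order the tendon list (median -0.18, camera adjusted p 0.000964; adjusted p 0.535 with an estimated correlation) gave 0.12, -0.29, -0.49, -0.38, -0.01 and -0.33. It was no longer called without control 1 (camera adjusted p 0.101) or mutant 2 (0.874). The adipocyte list (median -0.35, camera adjusted p 0.00497; adjusted p 0.525 with an estimated correlation) gave 0.02, -0.47, -0.56, -0.68, 0.26 and -0.70, and it too was no longer called without control 1 (camera adjusted p 0.542) or mutant 2 (0.0778). Smooth muscle, pericytes and marrow stroma (median -0.16, camera adjusted p 0.00796; adjusted p 0.456 with an estimated correlation) gave -0.06, -0.20, -0.34, -0.30, 0.06 and -0.27, and the call was lost without control 1 (camera adjusted p 0.721) or mutant 2 (0.696). Several lists were not called. These were peripheral nerve (median 0.19, camera adjusted p 0.276), skin (0.11, 0.496), Wnt signalling (0.06, 0.676), glycosaminoglycan synthesis (0.13, 0.143) and sex-linked genes (0.48, 0.945). Their adjusted p-values with an estimated correlation were 0.454, 0.579, 0.688, 0.624 and 0.961. BMP and TGF-beta signalling (median 0.03, camera adjusted p 0.897; adjusted p 0.935 with an estimated correlation) and immediate early genes (median 0.10, camera adjusted p 0.554; adjusted p 0.805 with an estimated correlation) were not called, and camera's direction was lower for both, opposite to the median. Without control 1 the nerve list was called higher (camera adjusted p 0.0113), as it was with array weights (0.0128), on arrays with Y-linked signal (0.0265) and without both control 1 and mutant 2 (0.00658), without mutant 3 glycosaminoglycan synthesis was called higher (0.0335), and without control 3 immediate early genes were called lower (0.0285). On arrays with Y-linked signal immediate early genes were instead called higher (median 0.30, camera adjusted p 0.00812).

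The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 187 features at an unadjusted p below 0.05 and at least 2-fold apart. Of the 10 splits 3 gave as many, and the highest other split gave 448. That split set mutant 2 and controls 2 and 3 against control 1 and mutants 1 and 3. The skeletal muscle scores parted the same way, at 2.26, 1.08 and 0.46 on control 1 and mutants 1 and 3 against -0.87, -0.97 and -1.96 on the others. The split was picked as the highest, and the count to expect without any structure was not computed. For gene lists the real split gave 25 calls, 2 of the 10 splits gave as many, and the highest other also gave 25.

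The first pattern is the lower osteoclast list, whose score differed by -0.81 (SE 0.40, linear fit on 6 arrays) and of whose 30 tested genes 4 also stand in another list. Without mutant 2 the difference stayed below 0, at -0.43 (SE 0.14, 3 residual degrees of freedom). With so few degrees of freedom, this does not rule out mutant 2 as the sole source. A smaller share of bone cells of both kinds is argued against by a fall larger than that of the osteoblast score, by -0.52 (SE 0.08). The osteoclast list was picked after its result was seen and was 1 of 5 lists with separated scores, which favours a difference that remains without mutant 2. With the marrow score as a covariate, which moved the median of the cartilage list from 0.25 to 0.06, the osteoclast difference stayed at -0.80 and its list past camera's preset threshold (median -0.59, adjusted p 5.25e-11), and control 3 joined a marrow score of -0.70 with an osteoclast score of 0.46. Less marrow still cannot be told apart from the genotype, because the SE of that difference grew to 0.57 with the marrow score going with the group (-0.93, SE 0.63), while its bright genes read 8.73 in controls and 8.01 in mutants (the globin Hba-a2) and 7.70 and 7.74 (the neutrophil receptor Csf3r). Csf3r was 1 of 2 genes above 0 in the neutrophil list, where 33 of 35 were below 0 with a median of -1.40, so it does not stand for that list. The fall was not particular to osteoclasts, since the macrophage list had a median of -1.05 against -0.65. Macrophage scores were 0.33, 0.78 and 0.34 on controls 1 to 3 and 0.05, -1.66 and 0.17 on mutants 1 to 3. Mutant 2 also had the lowest endothelial and osteoblast scores and the highest cartilage score. Whether these falls share a source was not tested. Fewer resorbing cells at mutant cartilage may be a candidate explanation, as a hypothesis that stands beside that of less marrow.

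The second pattern is the lower Notch pathway and target list, whose score differed by -0.27 (SE 0.18) and of whose 30 tested genes 3 also stand in another list. With the score of the endothelial list, less the genes both lists share, as a covariate the difference was -0.023 (SE 0.048, 3 residual degrees of freedom), so fewer endothelial cells may account for it. The full endothelial score was low on mutant 2 alone, at -1.05, against 0.11 and 0.12 on mutants 1 and 3 and 0.01 to 0.41 on controls. This covariate thus cannot tell fewer endothelial cells from mutant 2 alone. The brightest endothelial gene, Egfl7, read 5.07 in controls and 4.47 in mutants. Mutant 2 alone and less marrow cannot be told apart from the genotype, with differences of -0.089 (SE 0.061) without mutant 2 and -0.17 (SE 0.24) with the marrow score as a covariate. A subset of 5 target genes (Hes1, Hes5, Hey1, Heyl and Nrarp) was picked after their values were seen and so is not weighed. Its score differed by -0.79 (SE 0.32), by -0.36 (SE 0.09) with the endothelial covariate and by -0.47 (SE 0.07) without mutant 2. Reduced Notch signalling after loss of Adam10 stays open, as a hypothesis these tests do not single out.

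The third pattern is Cxcl12, which differed by -2.08 (SE 0.66, linear fit on this gene alone). The other marrow stromal markers (Lepr, Kitl, Foxc1, Ebf3 and Angpt1) were picked after their values were seen and went both ways, from Kitl at -0.66 (SE 0.37) and Ebf3 at -0.34 (SE 0.17) to Lepr at 0.07 (SE 0.19) and Angpt1 at 0.34 (SE 0.26). As the whole cause, a smaller share of stromal cells would lower them all about as much as Cxcl12, if no other cells expressed them. Which cells of these pieces expressed them was not tested. Their mean differed by -0.13 (SE 0.07), and Cxcl12 minus that mean by -1.95 (SE 0.63). These markers thus fell less than Cxcl12. Both they and Cxcl12 were picked after their values were seen, so this does not rule out a smaller share of stromal cells. Without mutant 2 the difference was -1.52 (SE 0.44, 3 residual degrees of freedom), but the gene was picked for its small p, so a large part played by that array stays open. A lower Cxcl12 level within cells of the mutant cartilage may be a hypothesis to follow up. A smaller share of stromal cells and a change in the share of Cxcl12-rich cells that lack these markers both stay open.

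Xist on mutant 1, an array with Y-linked signal, was above background at 2.03% of its mean on control 1 and mutant 3, and it was not above background on the other arrays with Y-linked signal. On mutant 3 the Y-linked genes Ddx3y and Eif2s3y were above background at 1.00% and 0.942% of their mean on the arrays with Y-linked signal, and neither was above background on control 1. The Y-linked genes Kdm5d and Uty were not above background on mutant 3 or control 1. Whether these samples were mixed was not worked out. The embryonic globin Hbb-y read -1.81 and -2.46 on mutants 1 and 3, and between -6.44 and -4.53 on controls and -5.88 on mutant 2.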
